A study of Homo sapiens with 12 samples.

How the data were processed

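The series holds 12 libraries of RNA from the polysome fractions of HEK293 cells, a human embryonic kidney line, transfected for 24 h with 5 ug of empty vector or of a plasmid for STING, the adaptor of cytosolic DNA sensing that is listed under its older symbol TMEM173. In polysome profiling, translation is halted with cycloheximide and the lysate is spun through a sucrose gradient, so that RNA carrying several ribosomes can be collected. Per the labels' protocols, polyadenylated RNA was copied and amplified by Smart-seq2 and sequenced in paired ends on an Illumina instrument. Total RNA was not analysed here, so each value is a level in the polysome fraction, and a change can come from the amount of an RNA or from its loading with ribosomes.

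The libraries form 6 groups of 2. A first experiment has vector and STING groups. A second, the knockout experiment, has vector and STING groups in wild-type cells and in cells labelled as knockouts of PERK (EIF2AK3), a kinase of the endoplasmic reticulum that phosphorylates eIF2alpha. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

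FPKM values (fragments scaled to transcript length and to the number of mapped fragments) of the first experiment were made by the authors with TopHat2 2.1.1 and Cufflinks 2.2.1 on genome build hg19, per the submitters' processing notes. The table lists 23284 symbols with decimals down to 0, and between 38.7% and 40.2% of symbols stand at 0 in a library. The deposited table of the knockout experiment lists 12421 symbols, has a lowest value of 1 in each library and does not name its unit. It was read as FPKM with values under 1 set to 1, from its tool-specific header and its values. Between 13.1% and 18.1% of symbols stand at that floor, so falls to it are understated. Gene annotation and filters are not given in the sources used here. The tables were tested separately, and levels set side by side across them are not on a shared scale.

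Neither table gives counts, so the absolute depth is unknown and no counting intervals are given. Among low values, ratios between libraries pile up at single values, as whole fragments would give. In the first experiment these put the relative depth of the libraries between 0.883 and 1, with vector library 1 as 1. In the knockout experiment the peaks were weaker and gave 0.824 to 1.28 relative to wild-type vector library 1. Within groups, log2 values of replicates correlated across genes with Pearson r from 0.948 to 0.991, and no pair shared an identical value above 1.

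All tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for genes with a mean of at least 1 over the libraries of the table. Genes with the same value in each library were left out, which in the knockout experiment dropped the 167 symbols at the floor throughout. That left 9464 genes in the first experiment and 12254 in the knockout experiment. Values were used as deposited, with no further scaling. Each group had its own mean, and the 8 libraries of the knockout experiment shared 1 estimate of the spread. Moderated statistics used an intensity trend and robust estimation (eBayes), were two-sided, and were adjusted by the method of Benjamini and Hochberg at 0.05. A fold change on this scale understates the change of genes with low values. The 5 contrasts were STING against vector in the first experiment, in wild-type cells and in knockout cells, the difference of the latter 2 effects (an interaction), and knockout against wild-type cells with vector. Per-gene errors are limma standard errors (SE); group levels are mean ± SD with n = 2.

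The test design, the gene lists and the rule for naming genes were fixed before the data were examined. The 29 lists, from textbook knowledge, covered targets of ATF4 and the integrated stress response, mRNAs with upstream open reading frames that resist eIF2alpha phosphorylation, endoplasmic reticulum chaperones, interferon-stimulated genes, NF-kB targets, survival genes, pro-apoptotic genes, p53 targets, secreted senescence factors, extracellular matrix genes, cytosolic ribosomal proteins, translation factors, DNA replication, mitosis, nuclear genes of oxidative phosphorylation, mitochondrially encoded mRNAs, cholesterol synthesis, the proteasome, glycolysis with hypoxia genes, autophagy with lysosomes, cytosolic heat shock proteins, immediate early genes, replication-dependent histones, nuclear noncoding RNAs, noncoding hosts of small nucleolar RNAs, components of the cGAS-STING-PERK pathway, and markers of haematopoietic cells, hepatocytes and fibroblasts. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, which sets a list against all other genes, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera relies on the residual degrees of freedom, 2 in the first experiment and 4 in the knockout experiment. A list can therefore miss the threshold there for lack of power, whatever the correlation between its genes, and the simulation below did not cover this version. This gave 26 testable lists in the first experiment and 25 in the knockout experiment. No mitochondrially encoded mRNA was listed in either table. Hepatocyte markers had 2 and 4 tested members and haematopoietic markers 3 in the first experiment, too few for a test. The nuclear noncoding RNAs and the hosts of small nucleolar RNAs had 0 tested members in the knockout experiment.

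Named genes were TMEM173 and EIF2AK3, any pathway component, up to 4 members of a list with the smallest unadjusted p, and the 10 largest rises and falls per contrast (5 for the genotype contrast) among genes past the threshold whose libraries did not overlap and whose higher mean reached 5. Where too few passed, genes with the smallest unadjusted p took their place and are said not to pass. Because most of these in the first experiment were small RNA entries, the largest changes without such entries were added after the data were seen.

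The procedure was tested on simulated data made from the real means and spreads, with independent normal noise and 200 genes changed. The changed genes were drawn from those with a mean log2 value above that of 5 FPKM, so recovery at lower levels was not measured. Of genes changed by 1 on the log2 scale, 74% were called in the first experiment, 36% for STING in wild-type cells, 21% for STING in knockout cells, 1% for the interaction and 36% for the genotype contrast. Of genes changed by 2, these shares were 97%, 98%, 97%, 64% and 99%. Of all calls, unchanged genes made up 10.2%, 6.25%, 3.23%, 9.72% and 6.16% in that order, from 1 simulation each, so the share of false calls can exceed the 5% aimed at.

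Alternatives were other pseudocounts and filters, median-of-ratios scaling, quantile normalization, another variance model, the replicate number as a block, only the groups of a contrast, and leaving out each library. Removal of trends on transcript length and GC content (from GENCODE transcripts, for 95.9% and 99.1% of tested genes), omission of small RNA entries and omission of TMEM173 were added after the data were seen.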

Results

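Polysome-fraction RNA was measured in 12 libraries of HEK293 cells, 2 in each of 6 groups. The series concerns a proposed pathway from cGAS and STING to PERK that would change which mRNAs are translated. The STING transcript checks the transfection. In the first experiment TMEM173 stood at 14.4 ± 0.836 FPKM with vector and 67205 ± 2896 with STING (SD, n = 2 each). In the knockout experiment it stood at 29.9 ± 9.55 and 41236 ± 815 in wild-type cells and at 33.6 ± 14.4 and 8925 ± 2244 in PERK knockout cells. The STING level was thus 4.62 times as high in wild-type as in knockout cells after transfection, and between 3.87 and 5.70 times for single pairs of libraries. EIF2AK3, the gene of PERK, was near or under the limit of both tables, with 0.370 ± 0.0221 FPKM with vector and 0.378 ± 0.123 with STING in the first experiment. In the knockout experiment it stood at the floor of 1 in 7 of 8 libraries and at 1.15 in knockout STING library 2, so these values cannot check the knockout label.

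**Figure D1:**
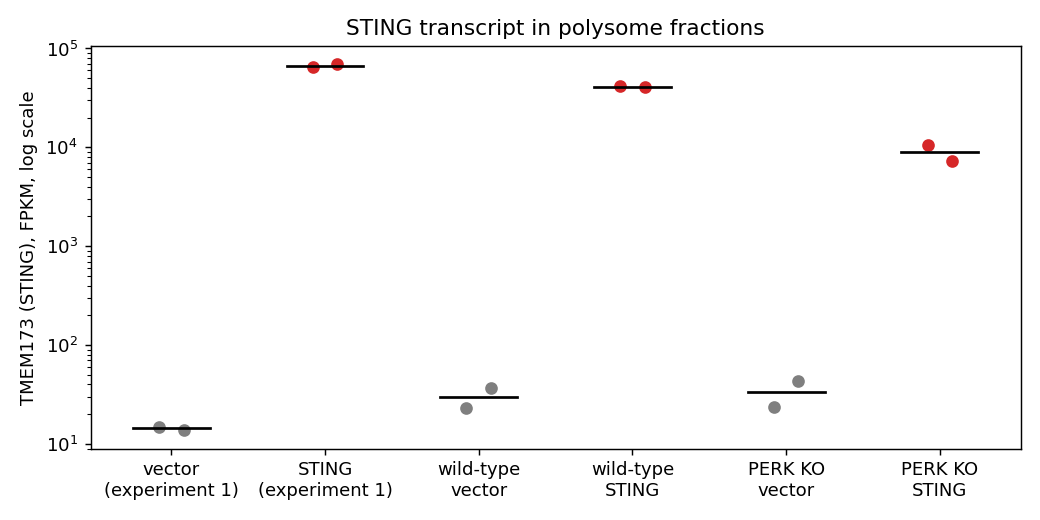
FPKM of TMEM173 on a log scale in each of the 12 libraries (points) with the mean of each group (lines). Knockout STING libraries, with a mean of 8925, lie below wild-type STING libraries, with a mean of 41236; the experiments come from separate tables.

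The first comparison asks which RNAs change in polysome fractions when STING is expressed. ISG15, an interferon-induced ubiquitin-like protein, rose from 81.3 ± 3.79 to 526 ± 35.5 FPKM (log2 change 2.68, SE 0.11, limma adjusted p = 1.6e-05). ATF3, a stress-induced transcription factor, rose from 10.7 ± 3.40 to 53.2 ± 2.58, and PMAIP1, the pro-apoptotic protein NOXA, from 32.3 ± 4.07 to 134 ± 11.5 (log2 changes 2.24 and 2.03). FOS, CSRNP1, ANKRD1 and IFIT2 also rose, with log2 changes of 2.09, 2.11, 2.33 and 2.08. UCP2, a mitochondrial carrier, fell from 70.5 ± 8.26 to 16.8 ± 4.09, TM7SF2, a sterol reductase, from 102 ± 3.81 to 27.9 ± 4.70, and SDSL, a serine dehydratase-like enzyme, from 24.6 ± 1.88 to 5.02 ± 0.595 (log2 changes -2.02, -1.84 and -2.09). These were chosen after the data were seen, from a ranking without small RNA entries. Of 9464 genes, 1117 passed with limma, 238 higher and 879 lower (78.7% lower). The lower share was 68.8% of 978 calls with median-of-ratios scaling and 55.5% of 777 with quantile normalization. Without the intensity trend and robust estimation 17 genes passed, 10 higher and 7 lower (41.2% lower). Without STING library 1, 42 genes passed, 33 higher and 9 lower; without STING library 2, 38 passed, 30 higher and 8 lower; without vector library 2, 686 passed. TMEM173 and ISG15 passed in each of the 4 fits that left out a library. TM7SF2 missed the threshold without STING library 2 (limma adjusted p = 0.0657), and the other genes named above missed it without STING library 1 and without STING library 2, with adjusted p of at most 0.164.

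**Figure D2:**
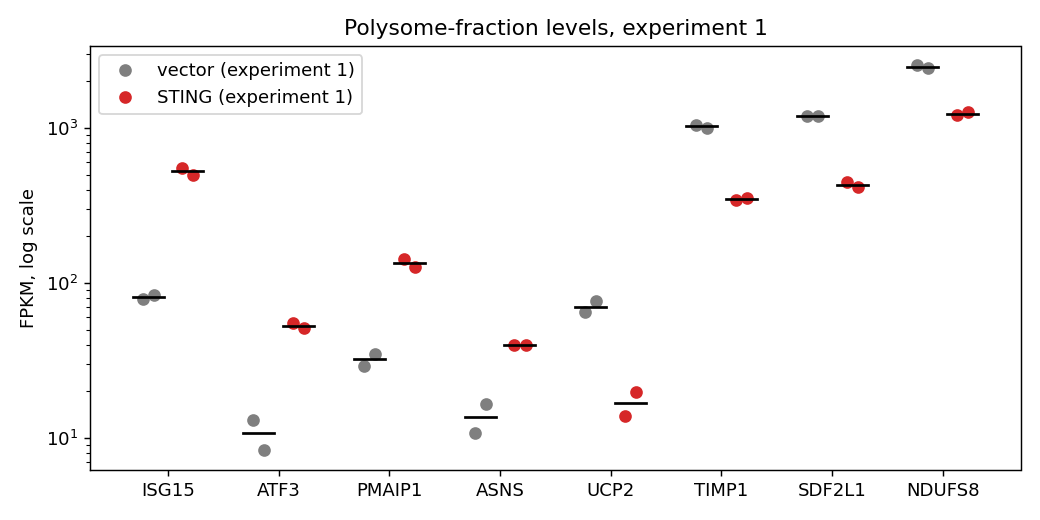
FPKM on a log scale of 8 genes in the vector and STING libraries of the first experiment (points, n = 2 each) with group means (lines). ISG15 goes from a mean of 81.3 to 526 and UCP2 from 70.5 to 16.8, and the libraries of the groups do not overlap for any gene drawn.

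The rule for the largest changes picked mostly small nucleolar and micro RNA entries listed at 0 in both libraries of a group, for which no fold is given. SNORD76 was listed at 0 in both vector libraries and at 451 and 1482 FPKM with STING, SNORA24 at 0 and at 51.7 and 56.6, and SNORA72 at 0 and at 50.2 and 54.9. Of 16 small RNA entries with a mean of at least 5 that were at 0 in both libraries of 1 group alone, 15 had values in the other group that, scaled to relative depth, stood in a whole-number ratio to within 1%, as whole fragments would give. In 5 of these, SNORA24, SNORA72 and SNORD70 included, that ratio was 1, so their small spread need not show agreement of replicates. SNORD35B, MIR3661, SNORA48, SNORD15A and SNORA71D were likewise listed at 0 with vector. SNORD70 was listed at 286 and 315 FPKM with vector and at 0 in both STING libraries, and SNORD104, SNORD49A, MIR3064, MIR647, SNORA65 and LOC100302640 had the same form. PRR4 rose to 9.68 ± 5.75 from 0.00115 ± 0.000462, whereas HIST1H4J fell from 30.1 ± 10.4 to 5.11 ± 1.75 and TMEM171 from 16.1 ± 2.09 to 2.64 ± 0.583. HCST stood at 11.3 and 6.31 FPKM with vector and at 0.983 and 0 with STING. Of 142 small RNA entries with a mean of at least 5, 78.9% were listed at 0 in some library, against 0.116% of other entries at that level. SNORD76, SNORD35B, MIR3661 and SNORA48 missed the threshold without either vector library (limma adjusted p up to 0.22004), PRR4 without STING library 2 (0.102), and SNORD104, SNORD49A, MIR647, LOC100302640, HCST, HIST1H4J and TMEM171 without either STING library (up to 0.166).

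Of 45 targets of ATF4 and the integrated stress response, 17 rose in the first experiment and 0 fell (26 and 1 adjusted over the list alone; camera adjusted p = 2.7e-11, adjusted p = 0.446 with an estimated correlation). Among them ASNS, asparagine synthetase, rose from 13.7 ± 4.06 to 39.9 ± 0.0835, PSAT1, a serine synthesis enzyme, from 8.10 to 21.8, TARS, threonyl-tRNA synthetase, from 6.18 to 16.8, and PPP1R15A, the GADD34 phosphatase subunit, from 10.1 to 25.1. DDIT3, the transcription factor CHOP, rose from 28.3 to 57.7. ATF4 itself stood at 448 ± 63.3 and 544 ± 33.7 and did not pass (limma adjusted p = 0.186). Of 20 mRNAs with upstream open reading frames, 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00675, adjusted p = 0.446 with an estimated correlation), and this list missed the threshold without vector library 2 (0.0771). Immediate early genes had 7 of 22 higher and 0 lower (10 and 0 adjusted over the list alone; camera adjusted p = 7.3e-07, adjusted p = 0.446 with an estimated correlation), including JUNB, from 4.29 to 12.9, and CYR61, from 5.33 to 19.7. NF-kB targets had 5 of 20 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0108, adjusted p = 0.446 with an estimated correlation), including NFKBIA, from 58.6 to 128. The single genes named here that passed missed the threshold without STING library 1 and without STING library 2, and DDIT3 also without vector library 2, with limma adjusted p of at most 0.190.

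Translation factors had 11 of 44 higher and 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 0.000109, adjusted p = 0.446 with an estimated correlation). EEF2, the translocation factor, rose from 113 ± 10.4 to 296 ± 39.4. Cytosolic ribosomal proteins had 9 of 78 higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00576, adjusted p = 0.736 with an estimated correlation), including RPL5, from 2144 to 3940; the list missed the threshold without vector library 2 and without STING library 1 (up to 0.884). Cytosolic heat shock proteins had 6 of 24 higher and 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 2.0e-05, adjusted p = 0.446 with an estimated correlation), with HSP90AB1 going from 36.9 to 73.5 and HSPB1 from 271 to 166. DNA replication genes had 3 of 39 higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00301, adjusted p = 0.446 with an estimated correlation), including MCM7, from 47.2 to 74.0. Mitosis genes had 1 of 35 higher and 1 lower, again unchanged when adjusted over the list alone (camera adjusted p = 0.00398, adjusted p = 0.446 with an estimated correlation). Pathway components had 3 of 13 higher and 0 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.0203, adjusted p = 0.446 with an estimated correlation). This call rested on TMEM173 itself, without which the adjusted p was 0.142, and was lost without vector library 2 (0.0771) and after the length and GC correction (0.0539); it was the 1 list that passed with fry, which tests against no change (0.0145). Apart from TMEM173, each single gene named here missed the threshold without STING library 1 and without STING library 2, and MCM7 also without vector library 2, with limma adjusted p of at most 0.228.

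Of 64 nuclear genes of oxidative phosphorylation, 25 fell and 2 rose (40 and 3 adjusted over the list alone; camera adjusted p = 2.2e-06, adjusted p = 0.446 with an estimated correlation). NDUFS8 and NDUFA13, subunits of complex I, fell from 2489 ± 73.1 to 1239 ± 34.1 and from 4336 ± 393 to 2078 ± 60.2. Cholesterol synthesis had 5 of 26 lower and 0 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.00656, adjusted p = 0.542 with an estimated correlation), including INSIG1, from 47.0 to 15.6. Replication-dependent histones had 7 of 25 lower and 0 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.0136, adjusted p = 0.446 with an estimated correlation), and missed the threshold without vector library 1 and without STING library 2 (up to 0.111). Histones and NF-kB targets also missed it among genes with a mean of at least 5 (0.0789 and 0.133). The respiration and histone lists missed the threshold with quantile normalization (0.214 and 0.157), and NDUFS8, NDUFA13 and INSIG1 missed it without STING library 1 and without STING library 2 (limma adjusted p up to 0.164).

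The other lists of the first experiment did not pass as groups. Endoplasmic reticulum chaperones had 10 of 32 lower and 0 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.0700), and SDF2L1 fell from 1195 ± 6.72 to 430 ± 22.2. Interferon-stimulated genes went both ways, with 4 of 24 higher and 5 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.877): IFI6 fell from 134 to 51.1, and the list had a median of -0.077, a mean of 0.063 and an upward test direction. Secreted senescence factors had 3 of 14 lower (4 adjusted over the list alone; 0.105), with TIMP1 falling from 1023 ± 34.4 to 348 ± 5.91. Counts higher and lower were 5 and 0 of 27 p53 targets (5 and 1 adjusted over the list alone; 0.0730), 3 and 1 of 25 pro-apoptotic genes (3 and 5; 0.947) and 0 and 2 of 19 survival genes (0 and 2; 0.563). They were 3 and 0 of 28 glycolysis and hypoxia genes (4 and 0; 0.0747), 2 and 1 of 17 matrix genes (3 and 1; 0.379), 2 and 2 of 42 autophagy and lysosome genes (2 and 2; 0.344) and 0 of 35 proteasome genes (0; 0.662). They were 1 and 0 of 11 nuclear noncoding RNAs (1 and 0; 0.379), 2 and 0 of 15 hosts of small nucleolar RNAs (2 and 0; 0.598) and 1 and 0 of 6 fibroblast markers (1 and 0; 0.967), whose median of -0.25 and mean of -0.14 were negative with an upward test direction. Brackets give counts adjusted over the list alone, then the camera adjusted p. Pro-apoptotic genes had a median of -0.053 and a mean of 0.021, and the proteasome a median of -0.083 and a mean of 0.0060, both with an upward test direction. With quantile normalization the proteasome (0.00113) and glycolysis and hypoxia (0.0252) passed upward and secreted factors (0.0348) downward, and p53 targets passed upward among genes with a mean of at least 5 (0.0237). After the length and GC correction chaperones passed downward (0.0246) and glycolysis and hypoxia upward (0.0285), and chaperones also without STING library 1 (0.0351). With a pseudocount of 5, chaperones (0.0474) passed downward and p53 targets (0.0457) and glycolysis and hypoxia (0.0485) upward. TIMP1 missed the threshold without STING library 1 (limma adjusted p = 0.0565), and SDF2L1 and IFI6 without either STING library (up to 0.108).

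**Figure D3:**
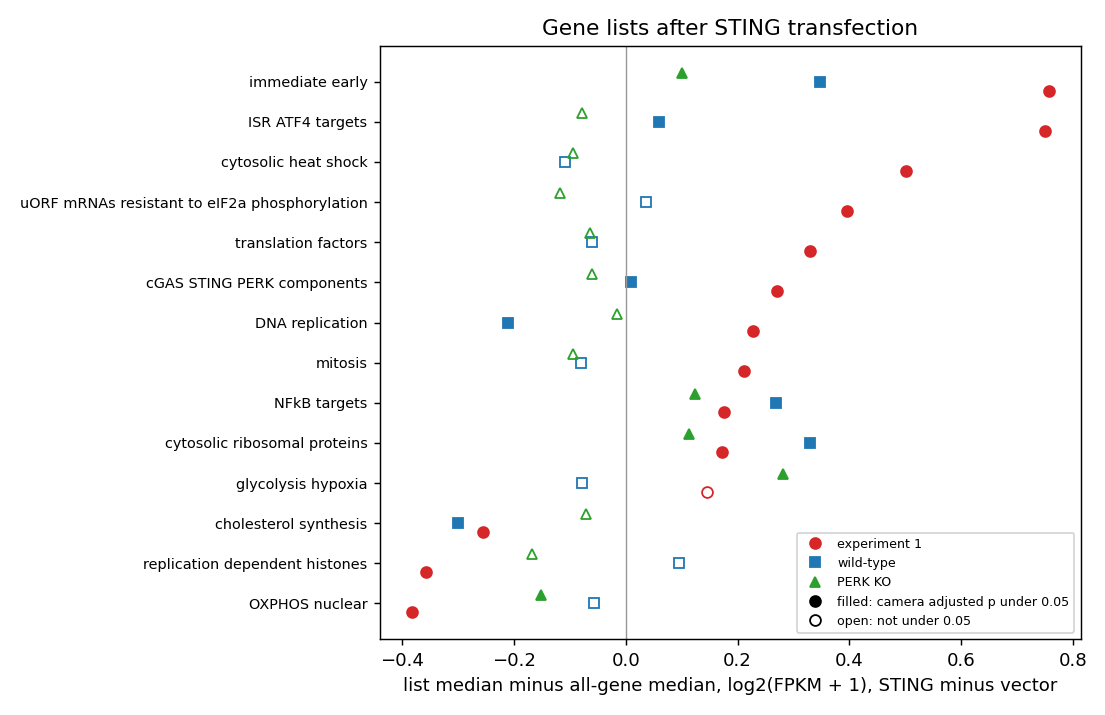
Median log2 change of 14 gene lists minus the all-gene median, STING against vector, in the first experiment, wild-type cells and PERK knockout cells. Filled symbols have a camera adjusted p under 0.05; targets of ATF4 lie at 0.75 in the first experiment and at 0.059 and -0.078 in the knockout experiment. NF-kB targets in wild-type cells lie at 0.27 with a median change of 0 before subtraction.

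The second comparison asks for the STING response of wild-type cells in the knockout experiment. Of 12254 genes, TMEM173 alone passed with limma (log2 change 10.42, SE 0.34, adjusted p = 3.3e-05), and 1570 had an unadjusted p under 0.05, 54 higher and 1516 lower. The median gene changed by -0.27, and by -0.02 with median-of-ratios scaling, so list values are relative to that median. Among genes that did not pass, ISG15 stood at 95.8 ± 18.6 with vector and 146 ± 31.2 with STING, NFKBIA at 77.2 ± 5.97 and 127 ± 1.13, MAFF at 2.07 and 6.85, ZFP36 at 16.2 and 37.0, and ATF3 at 18.4 and 27.4 (limma adjusted p = 0.384 each). UCP2 stood at 163 ± 25.3 and 86.9 ± 1.16, SDF2L1 at 418 and 221, C7orf50 at 194 and 88.0 and PTMA at 4416 and 2326 (0.384 each). ATF4 stood at 2727 ± 252 and 2666 ± 231. Without STING library 2 of wild-type cells, 2 genes passed.

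As groups, 10 of 25 lists passed in wild-type cells, with 0 members past the threshold in each except TMEM173 among the components, and the same counts adjusted over the list alone. Immediate early genes had a median change of 0.080, 0.35 above that of all genes (camera adjusted p = 2.0e-10, adjusted p = 0.0512 with an estimated correlation), the single list kept in each fit that left out a library. Ribosomal proteins had a median change of 0.062, 0.33 above that of all genes (2.8e-14, and adjusted p = 0.587 with an estimated correlation). NF-kB targets tested upward (0.000377, and adjusted p = 0.131 with an estimated correlation), with a median change of 0 and a mean of -0.042. A gene at the floor of 1 cannot fall, so it lies above the median gene without having risen; 2 of the 25 NF-kB targets were at the floor in each wild-type library. The 12 with a mean of at least 5 had a median change of -0.20 against -0.37 for all such genes (adjusted p = 0.00843). Cholesterol synthesis had a median of -0.30 against all genes (0.00363, and adjusted p = 0.760 with an estimated correlation). DNA replication and the proteasome tested downward, with medians of -0.21 and -0.29 against all genes (0.0202 each, and adjusted p = 0.826 with an estimated correlation). Targets of ATF4 (0.059; 0.0202, and adjusted p = 0.826 with an estimated correlation) and interferon-stimulated genes (0.090; 0.0298, and adjusted p = 0.433 with an estimated correlation) tested upward while their medians and means before that adjustment were negative. Components passed at 0.0202 (adjusted p = 0.587 with an estimated correlation; 0.285 without TMEM173), with a median of -0.26 and a mean of 0.34. Haematopoietic markers, genes of another cell type, passed at 0.0462 (adjusted p = 0.561 with an estimated correlation), with a median change of 0 and a mean of -0.035. Of these 8 genes 3 were at the floor throughout and 1 had a mean of at least 5, so the call may come from the floor. Among genes with a mean of at least 5, interferon-stimulated genes (0.172), DNA replication (0.228) and the proteasome (0.0867) missed the threshold. Without wild-type vector library 2, 3 lists passed, those lost including NF-kB targets, ribosomal proteins, cholesterol synthesis, DNA replication and the proteasome (adjusted p from 0.0593). Without knockout STING library 2, which enters through the shared spread, 5 passed. The proteasome (0.144) and targets of ATF4 (0.0596) were also lost without wild-type STING library 2, DNA replication (0.104) and interferon-stimulated genes (0.370) without wild-type STING library 1, and targets of ATF4 and components (0.0612 each) without wild-type vector library 1. Targets of ATF4 and interferon-stimulated genes were lost without knockout STING library 1 (0.0527 and 0.0509), and haematopoietic markers without knockout vector library 2 (0.0527) and each of the libraries above except wild-type STING library 2 and knockout STING library 1 (up to 0.501). Interferon-stimulated genes, components and haematopoietic markers were lost with median-of-ratios scaling (0.101, 0.0512 and 0.211), and haematopoietic markers also with a pseudocount of 0.1 (0.0542). With quantile normalization these 3 lists, ribosomal proteins (0.499), DNA replication (0.265) and the proteasome (0.0761) were lost, and p53 targets passed upward (0.00560). With median-of-ratios scaling chaperones passed downward (0.0169) and p53 targets upward (0.0389). With the replicate number as a block, chaperones (0.0285) and mitosis (0.0339) passed downward.

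In PERK knockout cells, TMEM173 was again the 1 gene past the threshold with limma (log2 change 8.05, SE 0.34, adjusted p = 0.000237), with 944 genes at an unadjusted p under 0.05 and a median change of -0.11. NDRG1, a hypoxia-induced gene, stood at 6.62 ± 0.837 with vector and 14.9 ± 1.60 with STING, GAPDH at 3276 and 4548, and PTMA at 4045 and 1643, none of which passed. ATF4 stood at 2230 ± 249 and 1488 ± 374 and DDIT3 at 56.3 ± 6.22 and 40.8 ± 4.16 (limma adjusted p = 0.598 and 0.614). Glycolysis and hypoxia genes had a median change of 0.18, 0.28 above that of all genes (camera adjusted p = 1.2e-06, adjusted p = 0.684 with an estimated correlation), with 0 of 30 past the threshold and 1 adjusted over the list alone; the list was lost without knockout STING library 2 (0.0767). NF-kB targets and ribosomal proteins tested upward, with medians of 0.12 and 0.11 against all genes and changes of 0.018 and 0.0054 (0.0110 each; adjusted p = 0.313 and 0.985 with an estimated correlation), as did immediate early genes and secreted senescence factors, at 0.10 and 0.15 against all genes (0.0167 each; adjusted p = 0.313 with an estimated correlation). Respiration genes tested downward, with a median of -0.15 against all genes (0.00845, adjusted p = 0.770 with an estimated correlation). These 5 lists had 0 members past the threshold, also adjusted over the list alone; immediate early genes had a median of -0.0063 and a mean of 0.060. Targets of ATF4 did not pass (0.723). Without knockout vector library 2, 3 genes and 3 lists passed, and without knockout STING library 2, 2 genes. NF-kB targets, ribosomal proteins and immediate early genes were lost without knockout vector library 2 and without knockout STING library 1 (up to 0.665). Secreted factors were lost without knockout vector library 1 or 2 or knockout STING library 2 (up to 0.294), and respiration without knockout vector library 1 or knockout STING library 2 (up to 0.112). Secreted factors also missed the threshold with median-of-ratios scaling (0.0533) and respiration among genes with a mean of at least 5 (0.126). Immediate early genes missed it after the length and GC correction (0.07998). Glycolysis and hypoxia was the 1 list that passed with quantile normalization. Among genes with a mean of at least 5, histones passed downward and components, TMEM173 included, upward (camera adjusted p = 0.0485 each). Matrix genes passed upward with a pseudocount of 5 (0.0374), and the proteasome downward with the replicate number as a block (0.0257).

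Whether the response differs between genotypes was tested by the interaction. No gene passed: 0 of 12254 with limma, the smallest adjusted p being 0.966. At an unadjusted p under 0.05 there were 474 genes, or 3.87%. That is no excess over the 5% given by this threshold when no gene differs. DDIT3 stood at 58.3 ± 0.754 with vector and 81.0 ± 0.887 with STING in wild-type cells, and at 56.3 and 40.8 in knockout cells (log2 difference -0.92, SE 0.24, adjusted p = 0.966). CHAC1, a target of ATF4, stood at 21.1 and 22.6 in wild-type and at 16.9 and 7.23 in knockout cells. As groups, glycolysis and hypoxia genes responded more upward in knockout than in wild-type cells (camera adjusted p = 3.3e-05), as did cholesterol synthesis (0.00710); the adjusted p was 0.916 for both with an estimated correlation. Ribosomal proteins (0.00513), histones (0.0128) and immediate early genes (0.0484) responded more downward, with adjusted p = 0.916, 0.638 and 0.653 with an estimated correlation. Immediate early genes had a median of 0.016 and a mean of -0.063. None of the 5 lists had a member past the threshold, 0 also adjusted over the list alone. Targets of ATF4 missed the threshold (0.0532) and passed downward after the length and GC correction (0.0168), without knockout vector library 1 (0.0176) and without knockout STING library 2 (0.0312). DNA replication (0.0508) passed upward after that correction (0.0336), with a pseudocount of 5 (0.0293) and without knockout vector library 2 (0.00037). Without wild-type vector library 2, 1 list passed, and 2 did without knockout vector library 1 or knockout STING library 2. Ribosomal proteins were also lost without wild-type STING library 1, histones without wild-type STING library 2, and immediate early genes without wild-type STING library 2 or wild-type vector library 1. Over these lists and libraries the adjusted p was at most 0.825. Among genes with a mean of at least 5, immediate early genes missed the threshold (0.0717), as they did with a pseudocount of 5 (0.0508). Ribosomal proteins missed it with quantile normalization (0.769), where the test direction turned upward. The lower STING level of the knockout libraries, 8925 against 41236 FPKM, goes with genotype in each of these comparisons, as would any other difference between the cells.

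With vector alone, knockout cells had lower CCL5, a chemokine, at 14.6 ± 3.80 against 120 ± 14.8 FPKM, and lower BMP2, a growth factor, at 1.23 ± 0.256 against 7.54 ± 0.0428. EPHA8, an ephrin receptor, was higher at 10.6 ± 0.0191 against 1.04 ± 0.0141, KRT8, a keratin, by 1.75 on the log2 scale (SE 0.19), and TMSB15A, a thymosin, at 99.6 ± 0.304 against 28.7 ± 2.64. GAP43, named after its values were seen because it completes the 6 calls, was higher at 3.85 against the floor of 1. In knockout cells with STING, GAP43 stood at 1.16 and 1.20, near that floor. Each of the other genes named here lay on the same side of wild-type cells with STING as with vector. These 6 genes, 4 higher and 2 lower, passed with limma at adjusted p from 0.0402 to 0.0444, with 1516 at an unadjusted p under 0.05. No gene passed without any 1 of the 4 wild-type libraries or without knockout vector library 1, 1 did without knockout vector library 2, and 3 did without either knockout STING library; 44 passed with median-of-ratios scaling and 0 when the 4 vector libraries were fitted alone.

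**Figure D4:**
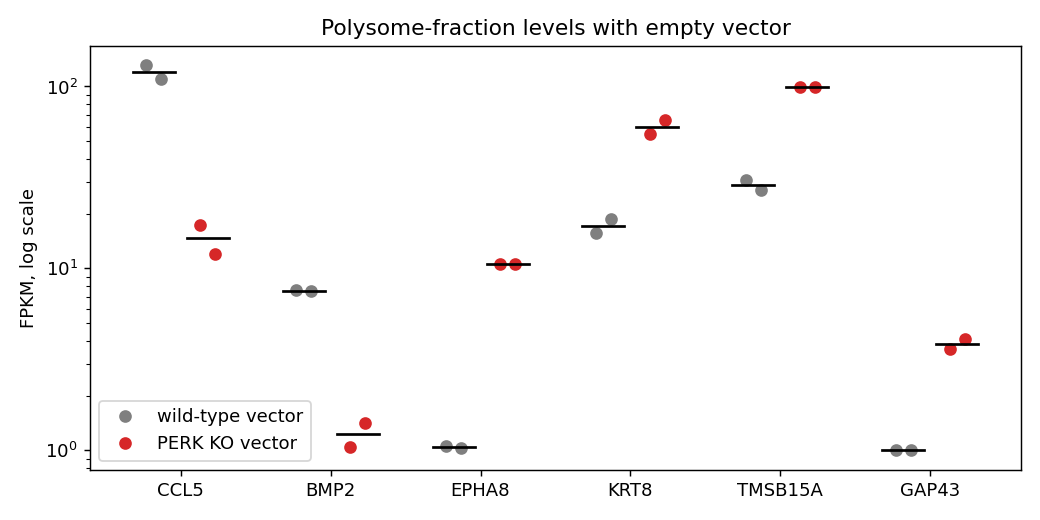
FPKM on a log scale of the 6 genes past the threshold between PERK knockout and wild-type cells with vector (points, n = 2 each) with group means (lines). CCL5 lies at a mean of 120 in wild-type and 14.6 in knockout cells, and values of 1 are the floor of the table.

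Among genes that missed the threshold, IFITM3, an interferon-induced membrane protein, stood at 14.8 ± 0.995 in knockout and 102 ± 16.3 in wild-type cells (limma adjusted p = 0.0521), OASL at 3.68 and 28.7 (0.0558) and IFNB1, interferon beta, at the floor of 1 and at 7.33 (0.0605). Interferon-stimulated genes as a list did not pass (camera adjusted p = 0.0749), with 0 of 34 higher and 1 lower, and 3 and 12 adjusted over the list alone. Tested against no change with fry they passed downward (0.0141). Against all genes they passed downward with median-of-ratios scaling (0.0281), after the length and GC correction (0.0427) and among genes with a mean of at least 5, where 15 of them had a median of -0.47 against all genes (0.0468). Targets of p53 had a median of -0.47 against all genes (camera adjusted p = 2.6e-06, adjusted p = 0.112 with an estimated correlation), with 0 of 28 past the threshold and 9 lower adjusted over the list alone; fry, which tests against no change, also passed downward (0.00179). CDKN1A, the p21 inhibitor, stood at 28.9 ± 7.64 against 73.2 ± 13.05 and TRIAP1 at 62.9 against 127. Glycolysis and hypoxia genes had a median of 0.47 against all genes (6.9e-10, adjusted p = 0.560 with an estimated correlation), with 7 of 30 higher adjusted over the list alone, ENO2 standing at 34.4 against 11.7. Ribosomal proteins (0.48; 1.2e-17, adjusted p = 0.635 with an estimated correlation) and cholesterol synthesis (0.23; 0.00257, adjusted p = 0.895 with an estimated correlation) also tested upward. Mitosis (0.00851), DNA replication (0.0336) and the proteasome (0.0336) tested downward, each with adjusted p = 0.895 with an estimated correlation. These 5 lists had 0 members past the threshold, also adjusted over the list alone. Mitosis, DNA replication and the proteasome were lost without wild-type vector library 2 and without knockout vector library 1 (up to 0.853), and cholesterol synthesis without knockout vector library 2 (0.142). Mitosis and DNA replication also missed it among genes with a mean of at least 5 (0.262 and 0.119), and DNA replication with quantile normalization (0.0942). Among those genes NF-kB targets (0.0468) and secreted factors (0.00977) passed upward, and chaperones passed downward with median-of-ratios scaling (0.0341).

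Across 8808 genes tested in both experiments, the STING effects of the first experiment and of wild-type cells correlated with Pearson r = 0.306 and Spearman rho = 0.203. Without TMEM173 r was 0.234. With TMEM173 kept, r ranged from 0.133 to 0.410 in fits without 1 library. Across 12254 genes, the effects in wild-type and knockout cells correlated with r = 0.289 and rho = 0.240, with a slope of 0.282 for knockout on wild-type cells; without TMEM173 r was 0.227 and the slope 0.226. That r fell to 0.00628 without knockout vector library 2 and to 0.0267 without knockout STING library 1, so it may rest on single libraries. The first experiment and knockout cells correlated with r = 0.158 and rho = 0.0909, and r was 0.0914 without TMEM173. These are correlations across genes, which are not independent replicates, and the compared effects share no libraries. TMEM173 was the 1 call shared by each pair of contrasts. As the transfected gene, its overlap was set by the design, and without TMEM173 each pair shared 0 calls. At an unadjusted p under 0.05, 454 genes were lower in both the first experiment and wild-type cells, against 252 expected from independent lists. In both wild-type and knockout cells 220 were lower, against 100.7 expected. Each of these effects fell with expression level (Spearman rho = -0.225 in the first experiment, -0.394 in wild-type and -0.330 in knockout cells). The wild-type and knockout contrasts also share 1 estimate of the spread, so a gene with a small spread can reach a low p in both. An excess over independent lists can therefore arise without a shared response.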

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

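The list tests of the difference between genotypes were planned, whereas the tests of explanations in this part were chosen after the results were seen.

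In 5 gene lists the STING response differed between wild-type and PERK knockout cells by the interaction test with camera: glycolysis and hypoxia genes (adjusted p = 3.3e-05), ribosomal proteins (0.00513), cholesterol synthesis (0.00710), histones (0.0128) and immediate early genes (0.0484), each call being lost with an estimated correlation (adjusted p = 0.638 to 0.916). Leaving out wild-type vector library 2 left 0 of the 4 lists other than glycolysis and hypoxia past the threshold, and leaving out knockout vector library 1 or knockout STING library 2 also ended each of those 4 calls, so they may rest on single libraries, whereas the glycolysis and hypoxia list passed in each of 8 such fits. Removing trends on transcript length and GC content left 5 of 5 lists past the threshold, which argues against those trends as the whole cause. The lower STING level in knockout cells cannot be told apart from loss of PERK for any of these lists, since the lowest wild-type STING library held 3.87 times the TMEM173 level of the highest knockout one, and for the glycolysis and hypoxia list the effects in wild-type and knockout cells, relative to all genes, summed to 0.26 (95% interval -0.15 to 0.68), which leaves open whether the response was larger in knockout cells. Between libraries that list's difference was 0.37 (-0.041 to 0.78), and ribosomal proteins missed the threshold with quantile normalization (adjusted p = 0.769) and immediate early genes among genes with a mean of at least 5 (0.0717). With vector alone, glycolysis and hypoxia genes, ribosomal proteins and cholesterol synthesis already differed between genotypes (camera adjusted p = 6.9e-10, 1.2e-17 and 0.00257, each lost with an estimated correlation). Other differences between the cells thus cannot be told apart from loss of PERK either.

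In the first experiment, 879 of 1117 calls were lower with STING, and 7 of 17 without the intensity trend and robust estimation. A single scaling factor per library may account for part of this excess, and only that of median-of-ratios scaling was tried. That factor does not account for the whole, since 68.8% of calls were still lower with it, against 78.7%. Nor do transcript length and GC content account for the whole, with 76.2% lower after their trends were removed. Whether a difference in the shape of the libraries' value distributions accounts for it cannot be told: with quantile normalization 55.5% of calls were lower, but that step would also remove a true excess of falls, and sorted log2 values differed between groups by 0.122 on average and at least 0.107, against 0.132 between the vector replicates and 0.0249 between the STING replicates. In fits without STING library 1 or 2, 21.4% of 42 and 21.1% of 38 calls were lower, from fewer samples and far fewer calls. An effect of STING stays open.

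Small RNA entries with a mean of at least 5 in the first experiment were listed at 0 in some library 678 times as often as other entries at that level, which is what unstable estimates of entries shorter than a sequenced fragment would give. Of 35 such entries at 0 in exactly 2 of the 4 libraries, 45.7% had both zeros in 1 group (95% exact interval 28.8% to 63.4%), against 33.3% by chance, so whether the zeros follow the group cannot be told apart from chance placement with this few entries. An effect of STING on single entries therefore stays open.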

How the results depend on the processing

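Corrections for length and GC content and the omission of small RNA entries or TMEM173 were added after the data were seen; the other alternatives were planned. Causes were not tested except where stated.

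In the first experiment, gene calls numbered 580 with no filter, where more genes were tested, and 17, 7 of them lower, without the intensity trend and robust estimation, against 1117. In fits without 1 library they ranged from 38 to 818, where the lone library of a group is assumed to vary like the others. Lists past the threshold there ranged from 10 to 13, against 13. For knockout against wild-type cells with vector, 6 calls became 17 with a pseudocount of 0.1, 32 with a mean of at least 5, 44 with median-of-ratios scaling, 24 with quantile normalization, 25 after the length and GC correction, 0 without trend and robust estimation and 0 with only the groups compared, and ranged from 0 to 3 without 1 library. STING calls ranged from 1 to 2 in wild-type and from 1 to 3 in knockout cells without 1 library. The interaction had 0 calls in each alternative run with limma. In the main fit 474 genes, or 3.87%, had an unadjusted p under 0.05, no more than that threshold gives when no gene differs.

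With an estimated correlation 0 lists passed in any of the 5 contrasts. That version has 2 or 4 residual degrees of freedom, so this cannot show whether correlation between genes explains the calls. With fry, which tests a list on its own, 1 passed in the first experiment, 0 for STING in wild-type cells, knockout cells and the interaction, and 2 for the genotype contrast. In wild-type cells 6 lists passed with a mean of at least 5 and 5 with quantile normalization, against 10, and in knockout cells 1 with quantile normalization, against 6. Without 1 library, lists ranged from 3 to 10 in wild-type cells, 3 to 7 in knockout cells, 1 to 7 for the interaction and 5 to 9 for the genotype contrast.

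ATF4 in wild-type cells, at -0.032 and not past the threshold, turned to 0.27 with median-of-ratios scaling and ranged from -0.13 to 0.062 without 1 library. TMEM173 in the genotype contrast, also not past it, ranged from -0.30 to 0.57. The correlation of the first experiment with wild-type cells, 0.306, was 0.409 with a pseudocount of 5 and ranged from 0.133 to 0.410 without 1 library. That of wild-type with knockout cells, 0.289, was 0.195 with quantile normalization and 0.428 with a pseudocount of 5, and ranged from 0.00628 to 0.439 without 1 library.

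Replicate numbers were not taken to pair the libraries: deviations of same-numbered libraries correlated at 0.0741 in the first experiment and at 0.0418 to 0.528 in the knockout experiment. There 5 of 6 pairs of groups exceeded 0.1, and in all 6 groups replicate 2 had the higher share of MTRNR2L entries and the lower FPKM sum, so a shared batch stays possible. With the replicate number as a block, gene calls were 1587 in the first experiment, 2 for STING in knockout cells and 105 for the genotype contrast, and 8 lists passed for the interaction, against 5, the added ones being targets of ATF4, DNA replication and respiration.

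Scaling to spike-ins, count models and summed duplicate symbols were not run, since the tables used here hold no spike-in entries, counts or duplicates. A filter at 0 moves nothing in the knockout table, whose floor is 1, and the variance model does not enter camera. Depth is unknown, and in the interaction the simulated recovery of 1% at a log2 change of 1 limits what its count can show.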

Other observations

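The tests in this part were chosen after the results were seen.

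Of 146 genes with TMEM numbers, a naming class of predicted membrane proteins, tested without TMEM173, 41 fell and 1 rose in the first experiment, and TMEM was the family with the smallest p among 43 families of numbered symbols with at least 20 tested members (camera adjusted p = 6.6e-07, adjusted p = 0.815 with an estimated correlation). The other families past the threshold were CD, with 4 of 22 lower and 0 higher (0.00852), HIST, with 12 of 43 lower and 1 higher (0.00883), MRPL and SLC. Genes named MRPL, proteins of the mitochondrial ribosome, had 14 of 49 lower and 0 higher (0.00883), and solute carriers named SLC had 22 of 165 lower and 3 higher (0.0477), with adjusted p = 0.824 for SLC and 0.815 for the other 3 with an estimated correlation. With quantile normalization the medians relative to all genes were -0.31 for TMEM, -0.38 for CD, -0.30 for HIST, -0.027 for MRPL and -0.20 for SLC. Without STING library 1 or without STING library 2, 0 members of these families passed, with TMEM medians of -0.31 and -0.36. In knockout cells 7 of 59 families passed, and those with the smallest p, MRPL and MRPS genes, lay 0.30 and 0.32 below all genes with STING (medians -0.30 and -0.32; camera adjusted p = 1.0e-07 and 0.000204, both adjusted p = 1.00 with an estimated correlation), with 0 of 47 and 0 of 29 past the threshold. With quantile normalization these medians were -0.13 and -0.20, and the MRPS median was -0.19 without knockout STING library 1. In wild-type cells MRPL and MRPS lay at -0.047 and -0.15 and missed the threshold (0.170 and 0.0712). There 5 of 59 families passed, RPL, RPS, OR and IL upward and DDX downward (adjusted p = 0.949 with an estimated correlation). These directions are relative to all genes, whose median change was -0.27. The OR median lay 0.27 above that, where genes that stay at the floor of 1 lie, so this call may come from the floor. In knockout cells OR also passed, 0.11 above an all-gene median change of -0.11 (camera adjusted p = 0.04996).

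The TMEM-numbered genes had a median of -0.31 relative to all genes. In 10000 random sets matched on transcript length, GC content and expression the set medians centred on -0.021, and the lowest was -0.23. On average, these properties thus do not give a fall of that size. The sets were drawn gene by gene, without the correlation within a family, and TMEM was picked for its smallest p. They therefore cannot show how unusual such a fall is for a family. A shared dependence on membrane targeting is a candidate explanation that was not tested. In wild-type and knockout cells the same class lay at -0.015 and -0.0030 relative to all genes, inside the matched ranges; the difference between experiments was not tested.

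A hypothesis is that the STING response of the first experiment recurs in wild-type cells of the knockout experiment. Of 837 genes lower in the first experiment, 75.5% lay below the all-gene median there (camera p = 1.4e-11, p = 0.113 with an estimated correlation), and of 214 higher genes 63.1% lay above it (2.4e-07, p = 0.269 with an estimated correlation). Both effects fall with expression level (Spearman rho = -0.225 and -0.394), and random sets of uncalled genes matched on expression, length and GC content had on average 60.4% and 39.0% on those sides, at most 65.1% and 48.4% in 1000 sets, against 75.9% and 63.4% for the called genes with a known length. The directions go with recurrence beyond those properties. Neither test passed with an estimated correlation, a version with few degrees of freedom, so recurrence stays open. In knockout cells 72.4% of the lower and 64.8% of the higher genes with a known length lay on those sides, where matched sets had on average 66.2% and 35.8%, and at most 71.5% and 46.5%. In the interaction, camera in limma gave unadjusted p of 0.114 for the lower and 0.0810 for the higher genes.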
